A study of Mus musculus with 8 samples.

How the data were processed

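RNA of LSK cells was taken from the bone marrow of 4 control mice and of 4 Msi2 KO mice, whose knockout is conditional, and was hybridised to 8 Affymetrix mouse arrays after biotin labelling, per the labels. The deposited values are log2 signals per probe set, normalized by the authors. The submitters' processing notes name RMA (background correction, quantile normalization and a summary of the probes of each probe set); its version is not given in the sources used here. Above 0 the values ran from 2.79 to 13.7. Of the 45101 probe sets, 20664 (45.8%) were exactly 0 on all 8 arrays and 0 probe sets were at 0 on some arrays only. RMA gives no such values, so an unstated step set them to 0. They carry no measurement and were left out, a departure from the plan, which had no filter. All 8 columns were placed by their labels, and no array was left out.

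Gene names came from the annotation of the array's probe sets, brought to current symbols through gene IDs and a RefSeq gene table of GRCm38.p6, which was used for names only. 34958 probe sets carried 1 gene name (34754 of them named through the gene ID), 932 several and 9160 none in the table used here. A gene was represented by its named probe set with the highest mean over all 8 arrays. Probe sets with several names or none and 64 AFFX control probe sets were left out of the gene fit. This left 10720 genes (5363 with more than 1 tested probe set), while 7474 genes were listed at 0 on all their probe sets. The fit on probe sets used 24404.

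Genes and probe sets were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Every adjusted p of a gene or list is from limma unless another test is named. 29 gene lists of lineages, signalling, cell cycle and metabolism with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Members were also adjusted over the list alone. Beside camera stand camera with an estimated correlation, camera on ranks, and fry, which tests whether the genes of a list move one way on balance and makes no comparison with other genes. Exact permutation tests used all 70 assignments of the arrays, with a smallest two-sided p of 0.0286, or the 30 that exchange labels only among arrays of like Xist level. Means are given with SD or SE as named, intervals cover 95%, and list means are the mean log2 difference of the measured members.

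The tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names 10 genes per direction with the smallest p where none passes the threshold. It also names 2 members of each list with the smallest p and a fixed set of genes of interest to stem cell biology. For the 10 per direction, clone-like symbols, near-identical gene copies and genes represented by a probe set ending in _s_at or _x_at were skipped. The plan did not spell out the last of these skips. The lists came from textbook knowledge and not from these arrays. The alternatives were repeated quantile normalization, median centring, leaving out genes below the median level, the mean of all probe sets of a gene, leaving out probe sets shared between transcripts, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array, and a fold change of at least 1.5. Chosen after the data were seen were Xist as a covariate, the arrays with high or low Xist alone, keeping probe sets listed at 0 in the adjustment, and exact permutation of the list means. The 2 further lists in the closing section were also chosen then.

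The procedure was tested on simulated data of 10720 genes for the comparison of Msi2 KO with control, with 200 genes changed. It recovered 90 (45.0%) at a log2 change of 1, 188 (94.0%) at 2 and 197 (98.5%) at 3, with 4, 11 and 11 false calls. With 5 lists shifted by 0.5 it recovered 5, and of 21 lists that shared no gene with them it called 0. The simulated genes varied independently of each other and with the same spread in both groups. The simulation therefore does not show how often camera calls lists falsely where genes vary together, as in the real arrays. Nor does it show how many genes are recovered where a gene varies more in KO than in control, as Msi2 did (SD 1.21 and 0.12).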

Results

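Gene expression was measured on 8 Affymetrix mouse arrays in LSK cells from bone marrow. LSK cells are lineage-negative cells that carry Sca-1 and Kit, a fraction that holds the blood stem cells and early multipotent progenitors. 4 arrays came from normal control mice and 4 from mice with a conditional knockout (KO) of Msi2, which encodes the RNA-binding protein Musashi-2. The table held 45101 probe sets, of which 20664 (45.8%) were listed at 0 on all 8 arrays and were left out. The remaining values gave 10720 genes and 24404 probe sets to test, and median log2 signals of 7.03 to 7.07 per array. Correlations between arrays ran from 0.942 to 0.983, and the number of arrays limits the precision. Msi2 KO 3 stood apart from the other arrays, at 50.5 on the first principal component (32.4% of the variance) against -26.7 to 11.0 elsewhere. It also had the highest 3' minus 5' difference of actin (0.287, others -0.118 to 0.133), the lowest signal of the bioB spike-in (9.64, others 9.98 to 10.34) and the lowest array weight (0.445, others 0.608 to 2.17). Its 3' minus 5' difference of Gapdh (1.70, others 1.35 to 1.85) and its Cre spike-in (13.68, others 13.57 to 13.73) lay within the range of the others. Xist, the transcript of the inactive X chromosome, was low on control 1 (4.06), Msi2 KO 1 (4.19) and Msi2 KO 2 (3.83) and lay between 11.21 and 11.82 on the other arrays. The Y-linked gene Eif2s3y was the mirror image, at 8.05 to 8.14 on these 3 arrays and 3.36 to 3.62 on the others, so 1 control and 2 KO arrays read as male and the rest as female.

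The comparison of the 2 groups asks how the loss of Msi2 alters gene expression in LSK cells, and it starts with the deleted gene itself. On its 4 bright probe sets, Msi2 signal was lower on all 4 KO arrays than on every control array, to an uneven degree. Averaged over its 4 bright probe sets, Msi2 stood at 72.6%, 63.4%, 15.1% and 40.5% of the control mean on Msi2 KO 1 to Msi2 KO 4, while the controls lay between 91.1% and 111%. For the brightest probe set, 1421230_a_at, the log2 signal was 11.53 ± 0.12 (SD, n = 4) in controls and 10.42 ± 1.21 (SD, n = 4) in KO, a difference of -1.12 with a 95% confidence interval of -2.24 to 0.01. The other bright probe sets gave differences of -1.44 (1435520_at), -1.30 (1435521_at) and -1.30 (1436818_a_at). The dim probe set 1443008_at went from 5.44 ± 0.73 to 4.49 ± 0.34 (SD, n = 4 each), and its groups overlapped (two-sided exact permutation p 0.0857). The groups did not overlap for any of the 4 bright probe sets, with a two-sided exact permutation p of 0.0286 for each, the smallest that 4 arrays against 4 can give. In the limma fit across all genes Msi2 missed the threshold, at an adjusted p of 0.442. Its difference without Msi2 KO 3 was -0.55, with an adjusted p of 0.482 (0.220 to 0.791 over all alternatives). Msi2 probe sets 1421231_at, 1441185_at and 1458136_at, and the related gene Msi1, were listed at 0.

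**Figure D1:**
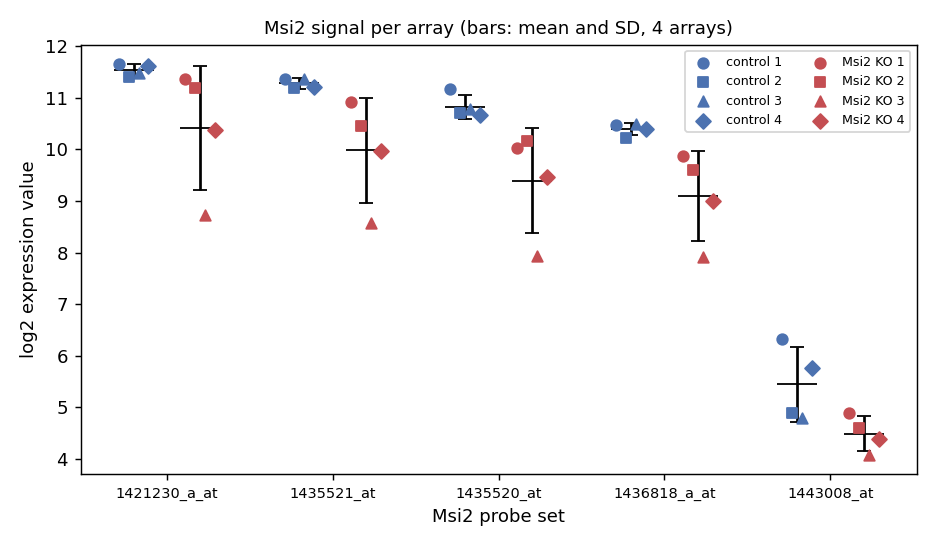
Log2 signal of the 5 measured Msi2 probe sets on each array, controls beside Msi2 KO, with the mean and SD of each group. On the 4 bright probe sets every KO array lies below every control, with Msi2 KO 3 the lowest.

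No single gene passed the adjusted threshold of limma (0 of 10720, smallest adjusted p 0.176). The genes named here are therefore those with the smallest p in each direction after the skips of the naming rule, and all of them missed the threshold. On the higher side, Fcer1a, the alpha chain of the IgE receptor of mast cells and basophils, read 4.27 ± 0.60 in controls and 6.87 ± 0.64 in KO (SD, n = 4 each). Its controls lay between 3.59 and 5.05, near the level of Eif2s3y or Xist on arrays that lack them, so no fold is given. Zfpm1, the cofactor of the erythroid and megakaryocytic factor GATA1, was 2.07-fold higher, and Blvrb, a biliverdin reductase of red cells, was 3.29-fold higher. 4 of the 10 act in mitochondria. These are Atp5g1 (a subunit of ATP synthase, 0.75 ± 0.14, log2 difference with SE), Gtpbp3 (tRNA modification, 0.65 ± 0.11), Rpusd4 (RNA pseudouridylation, 1.11 ± 0.22) and Bola3 (iron-sulphur cluster assembly, 0.62 ± 0.13). Znrd2 (0.75), Mogs (0.76) and Ccdc71l (0.81) complete the higher side.

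On the lower side, Fscn1, an actin-bundling protein, read 4.89 ± 0.03 in controls and 3.58 ± 0.36 in KO (SD, n = 4 each). Psma8, a proteasome subunit, went from 8.12 ± 0.20 to 6.55 ± 0.43, a 2.97-fold difference. Tgfbr1, the type I receptor of TGF-beta, went from 8.26 ± 0.09 to 7.51 ± 0.14, and Mycn, a MYC family transcription factor, from 8.61 ± 0.23 to 7.70 ± 0.23. The others were Itga9 (an integrin, -1.53), Clec4e (a C-type lectin, -1.38), Tha1 (-1.35), Ccdc173 (-1.06), Tubb6 (a tubulin, -0.84) and Gpr65 (a proton-sensing receptor, -0.74). Fscn1 was near background in both groups (4.89 in controls and 3.58 in KO), and Itga9 (4.34) and Clec4e (4.68) were near it in KO. For each of these 20 genes all 4 KO arrays lay outside the range of the controls, and adjusted p lay between 0.176 and 0.230. Across all genes, limma gave 1222 at an unadjusted p under 0.05 (11.4%), 615 higher and 607 lower in KO, where 536 would be expected by chance. KO and control arrays did not overlap for 762 genes (7.11%), 389 above and 373 below, and chance gives 2.86%. Of the single probe sets, limma passed 0 of 24404, with 2371 at an unadjusted p under 0.05. The nearest was 1432344_a_at of Aplp2, 1.75 higher at an adjusted p of 0.0609, which passed under 4 alternatives. In the gene fit a brighter probe set stands for Aplp2, and there no gene had an adjusted p below 0.176. Without Msi2 KO 1 a gene outside the naming rule, Zg16, passed in both fits, with a log2 difference of 3.56. With Xist as a covariate 5 genes passed: Fcer1a, Fscn1 and Psma8 and, outside the rule, Mt1 and Nhsl1.

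Gene lists fixed in advance gave a pattern by lineage: erythroid genes were higher in KO, and genes of stem cells and of lymphoid-primed progenitors were lower. Of the 29 lists tested, 10 passed camera with its preset correlation, 5 higher and 5 lower. None of the 10 passed with an estimated correlation, by the rotation test fry or by exact permutation of the list means after adjustment. The adjusted exact permutation test could hardly pass, since its smallest p before adjustment is 0.0286. Many of the 29 lists would have to reach that minimum, and 4 did. Without Msi2 KO 3, 6 lists passed, 4 of them among the 10. With an estimated correlation 0 lists passed when any 1 array was left out (lowest adjusted p 0.326). Of the 35 splits of the 8 arrays into 4 and 4, 11 gave at least as many lists. The list means, medians and tests had the same sign for all 29 lists.

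All 19 measured members of the Erythroid genes were higher in KO, by 0.99 on average (adjusted p 1.51e-09; adjusted p = 0.562 with an estimated correlation). 4 members passed when adjusted over the list alone, and 0 over all genes. Kel, Rhag and Slc4a1 had a group mean below 5, near background, and the other 16 members were higher by 0.99 as well. Those that passed were Zfpm1, Blvrb, Klf1, the erythroid Krüppel-like factor (1.61 ± 0.47, SE), and Gata1, the main erythroid transcription factor (1.37 ± 0.37, SE). The list mean stood 0.34, 0.66, 1.97 and 0.97 above the control mean on Msi2 KO 1 to Msi2 KO 4, and the controls lay between -0.43 and 0.44, so the groups overlapped (two-sided exact permutation p 0.0571). Without Msi2 KO 3 the mean was 0.66 higher, with an adjusted p of 1.20e-06 (4.87e-11 to 1.20e-06 over the 8 left-out arrays). In that setting adjusted p = 0.579 with an estimated correlation, and the two-sided exact permutation p was 0.114. Of the Mast cell and basophil genes, 5 of 7 were higher, by 0.87 on average (adjusted p 0.0178; adjusted p = 0.562 with an estimated correlation). Fcer1a and Cpa3, the mast cell carboxypeptidase (1.87 ± 0.42, SE), passed over the list alone. Without Fcer1a and Ms4a2, which had a group mean below 5, the mean of the other 5 members was 0.42. Without control 1 the mast cell list missed the threshold (mean 0.67, adjusted p 0.0973, range 0.00551 to 0.0973 over the 8 left-out arrays).

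Of the HSC-enriched genes, markers of blood stem cells, 22 of 25 measured members were lower in KO, by -0.54 on average (adjusted p 4.49e-05; adjusted p = 0.562 with an estimated correlation). Adjusted over the list alone 3 passed, Gstm2, the lectin Clec1a and the endothelial and stem cell receptor Robo4 (-0.96 ± 0.27, SE), and 0 passed over all genes. Clec1a (4.25 in controls, 3.65 in KO) was not shown to lie above background, and Gstm2 (5.31 and 4.50) was near it in KO. These, Hoxb5 and Neo1 had a group mean below 5, and of the other 21 members 18 were lower, with a mean of -0.46. The list mean stood at -1.46 on Msi2 KO 3 and between -0.26 and -0.21 on the other KO arrays, all below the lowest control at -0.20 (two-sided exact permutation p 0.0286). Without Msi2 KO 3 the mean was -0.23 and the list missed the threshold, at an adjusted p of 0.0674 (3.29e-06 to 0.0674 over the 8 left-out arrays). The HSC-enriched list missed it as well when genes below the median level were left out (mean -0.38, adjusted p 0.127, 3.26e-07 to 0.562 over all alternatives). Some lower members, such as Tek, Tie1, Esam and Robo4, are also expressed in endothelium. The stromal and endothelial list was lower on all 4 KO arrays than in the controls, by -0.50 on average (two-sided exact permutation p 0.0286). That list missed the camera threshold (adjusted p 0.0872; adjusted p = 0.562 with an estimated correlation). At the preset correlation it passed camera with the replicate block (adjusted p 0.0211), with Xist as a covariate (0.0195) and in the high-Xist arrays (0.0252). Mecom (-0.63), Hlf (-0.76 ± 0.60, SE), Meis1 (-0.22), Hoxa9 (-0.35) and Slamf1 (-0.13) did not pass. These were, without Msi2 KO 3, -0.07, -0.03, 0.08, -0.20 and 0.25, in the same order.

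The Multipotent and lymphoid-primed progenitor genes were lower for 13 of 14 members, by -0.48 on average (adjusted p 0.00139; adjusted p = 0.562 with an estimated correlation), and 0 passed over the list alone. Dntt, the terminal transferase of lymphoid progenitors, went from 10.96 ± 0.27 to 9.14 ± 1.18 (SD, n = 4 each), a 3.53-fold difference. Mn1, a transcriptional cofactor, read 6.28 in controls and 4.90 in KO, where it nears background, so no fold is given. With Ccr9 and Rag2 it had a group mean below 5, and the other 11 members were all lower, with a mean of -0.46. The receptor Flt3 differed by -0.62, Notch1 by -0.75, Cd48 by -0.41 and Cd34 by -0.22. The differences without Msi2 KO 3 were -0.12 for Flt3, -0.50 for Notch1 and -0.02 for Cd34, and Flt3 was above every control on 1 KO array. The list mean was -1.23 on Msi2 KO 3, -0.53 on Msi2 KO 4, -0.17 on Msi2 KO 1 and near 0 on Msi2 KO 2, and without Msi2 KO 3 it was -0.23 at an adjusted p of 0.0498 (1.39e-05 to 0.0498 over the 8 left-out arrays). All 5 measured B cell genes were lower, by -0.52 on average (adjusted p 0.0185; adjusted p = 0.562 with an estimated correlation), with Vpreb1, part of the surrogate light chain, at -1.19 ± 0.47 (SE) and Cd79b at -0.42. The B cell list missed the threshold without Msi2 KO 3 (mean -0.32, adjusted p 0.171) or without control 2 (mean -0.43, adjusted p 0.0548), within a range of 0.00904 to 0.171. Of the MLL and Hox programme genes, 15 of 18 were lower, by -0.24 on average (adjusted p 0.0178; adjusted p = 0.562 with an estimated correlation), led by Erg (-0.74 ± 0.28, SE) and Mef2c (-0.43), both transcription factors (-0.46 and -0.28 without Msi2 KO 3). That mean without Msi2 KO 3 was -0.08 and adjusted p 0.310 (0.00436 to 0.310).

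**Figure D2:**
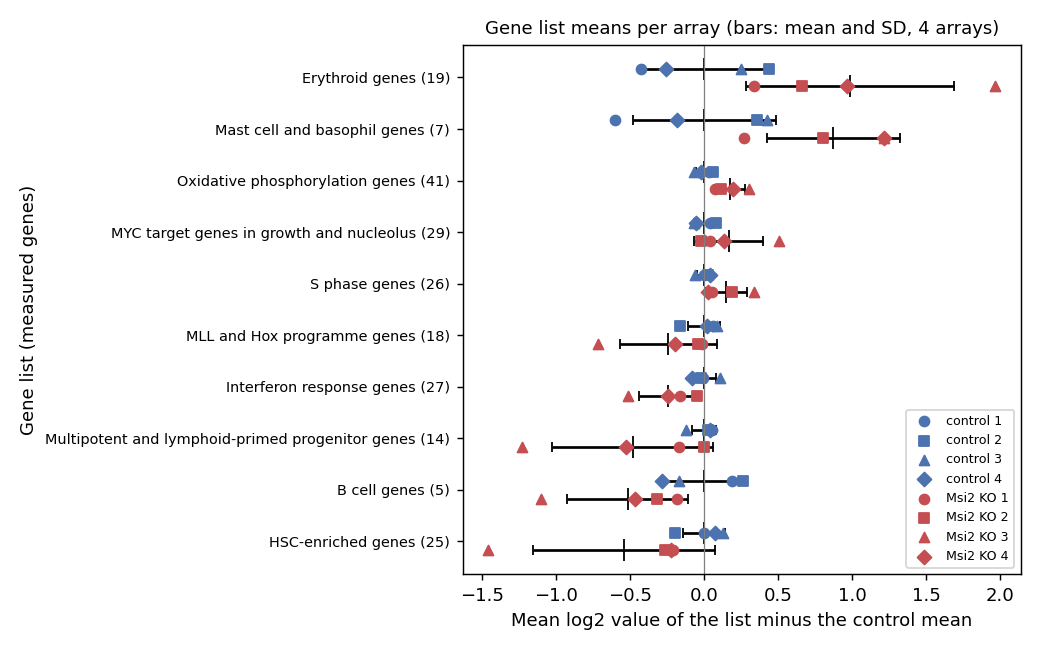
Mean log2 value of each of the 10 lists that passed camera, per array, minus the mean of the controls, with the mean and SD of each group. Msi2 KO 3 lies farthest from the controls in most lists, at 1.97 for the erythroid genes and -1.46 for the HSC-enriched genes.

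**Figure D3:**
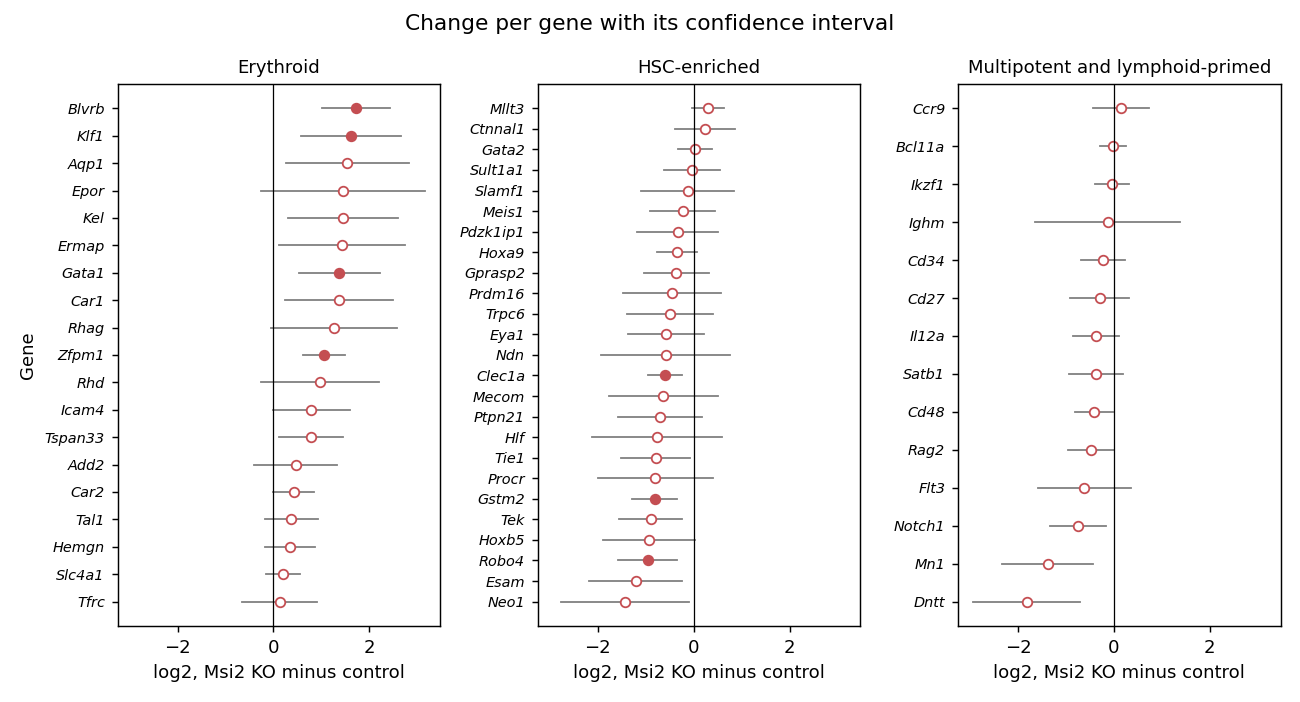
Log2 difference, KO minus control, of each measured member of the erythroid, HSC-enriched and multipotent and lymphoid-primed lists, with its 95% confidence interval. Filled points passed when adjusted over the list alone, 4 erythroid and 3 HSC-enriched genes, and none passed over all genes.

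The lists of oxidative phosphorylation, MYC targets and S phase passed camera with small differences. Of the Oxidative phosphorylation genes, 37 of 41 were higher, by 0.17 on average, or 1.13-fold (adjusted p 4.49e-05; adjusted p = 0.562 with an estimated correlation), with 0 past the threshold over the list alone. Cyc1, cytochrome c1 of complex III, was 0.58 ± 0.16 (SE) higher and Ndufs7, of complex I, 0.46 ± 0.15. This list passed without any 1 of the arrays (8.83e-06 to 0.00320), and all 4 KO arrays lay above the controls (two-sided exact permutation p 0.0286). Of the MYC target genes in growth and nucleolus, 23 of 29 were higher, by 0.17 (adjusted p 0.0128; adjusted p = 0.645 with an estimated correlation), with Rrp9 at 0.42 and Nop2 at 0.47, both of ribosome assembly. Of the S phase genes, 17 of 26 were higher, by 0.15 (adjusted p 0.0185; adjusted p = 0.567 with an estimated correlation), with the primase subunit Prim1 at 0.39 and the replication factor Cdc45 at 0.62. Both missed the threshold without Msi2 KO 3, the MYC list at a mean of 0.05 (adjusted p 0.364, range 0.000347 to 0.364) and the S phase list at 0.09 (adjusted p 0.222, range 0.00537 to 0.222). The S phase list missed it also without control 3 (mean 0.13, adjusted p 0.0782).

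Other lists of growth did not pass. The G2 and M phase genes had 14 of 26 members higher (mean 0.03, adjusted p 0.753), with Cenpa at 0.58, Ndc80 at -0.26 and Mki67 at -0.12. The Cytosolic ribosomal protein genes had 25 of 35 higher (mean 0.09, adjusted p 0.0789; adjusted p = 0.562 with an estimated correlation), with Rps25 at 0.76 and Rps10 at 0.23. They passed without Msi2 KO 2 (mean 0.10, adjusted p 0.0484, range 0.0484 to 0.159), with an intensity trend and on ranks. All 4 KO arrays lay above the controls for this list (two-sided exact permutation p 0.0286). Of the Cell cycle inhibitors and quiescence genes 12 of 18 were lower (mean -0.15, adjusted p 0.0872). Over the list alone 3 passed, the inhibitor Cdkn1a (-0.71 ± 0.18, SE), the repressor Gfi1 (-0.60) and the retinoblastoma gene Rb1 (0.83). That list passed without control 1 (mean -0.21, adjusted p 0.0270, range 0.0270 to 0.540). The Glycolysis and hypoxia genes (mean -0.09, adjusted p 0.357; Slc2a3 -0.52, Aldoa 0.31) and the Cholesterol synthesis genes (mean -0.04, adjusted p 0.487; Cyp51 -0.67, Insig1 -0.55) did not pass either. The cholesterol list passed camera at the preset correlation when genes below the median level were left out (adjusted p 0.0237). With an estimated correlation and all genes its adjusted p was 0.896. Slc2a3 turned to 0.33 when probe sets shared between transcripts were left out.

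The Interferon response genes were lower for 20 of 27 members, by -0.24 on average (adjusted p 0.0161; adjusted p = 0.562 with an estimated correlation). The interferon-induced GTPase Igtp went from 8.18 ± 0.22 to 7.43 ± 0.11 (SD, n = 4 each) and was the only member to pass over the list alone, with Ifi47 at -0.44. The mean without Msi2 KO 3 was -0.15 and adjusted p 0.144 (0.00382 to 0.144). Of the TGF-beta pathway components 13 of 21 were lower, by -0.15 (adjusted p 0.0737), and over the list alone Tgfbr1 passed. Smad1 was at -0.68, Smad3 at -0.18 and Tgfbr2 at 0.04. That list passed without control 2 (mean -0.20, adjusted p 0.0185), without Msi2 KO 1 (-0.22, 0.0103) or without Msi2 KO 2 (-0.20, 0.0311), within a range of 0.0103 to 0.364. The TGF-beta target genes had 9 of 14 lower (mean -0.10, adjusted p 0.733), with Ski at 0.46. Of the Notch pathway and target genes 10 of 12 were lower (mean -0.22, adjusted p 0.0839), with Notch1 at -0.75 and the ligand Jag2 at -0.62. They passed without Msi2 KO 1 (mean -0.29, adjusted p 0.0206, range 0.0206 to 0.310).

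Markers of other cells showed no common direction. The Macrophage and monocyte genes were higher for 9 of 13 members (mean 0.59, adjusted p 0.0817). Cd68 (1.09 ± 0.26, SE) and the lysozyme gene Lyz2 (-0.79 ± 0.22) passed over the list alone, in opposite directions. That list passed without Msi2 KO 3 (mean 0.92, adjusted p 0.000788) and without control 3 (0.74, 0.0392), within a range of 0.000788 to 0.523, but with an estimated correlation adjusted p = 0.537 and 0.661 in these settings. The Dendritic cell and MHC class II genes were higher for 5 of 7 (mean 0.15, adjusted p 0.753), and passed without Msi2 KO 3 (mean 0.59, adjusted p 0.000901, range 0.000901 to 0.988; adjusted p = 0.326 with an estimated correlation). Their member Cd74 was 5.83 on Msi2 KO 3 and 8.40 to 8.87 on the other KO arrays. The Myeloid-primed progenitor genes had 11 of 18 higher (mean 0.07, adjusted p 0.896), with Mpo at -0.03 and the cytokine receptor Csf2rb at -0.61. The Megakaryocyte and platelet genes had 9 of 16 higher (mean 0.10, adjusted p 0.733), with Selp at -1.10, Ppbp at 0.75 and Pf4 at 1.02 ± 0.56 (SE). Stromal and endothelial genes were lower for 5 of 6 (mean -0.50, adjusted p 0.0872), with Pecam1 at -0.64 and Bgn at -0.80. Mature neutrophil genes were higher for 5 of 5 (mean 0.20, adjusted p 0.487; S100a8 0.35, Padi4 0.36). T and NK cell genes were lower for 3 of 5 (mean -0.07, adjusted p 0.753; Cd247 -0.25, Nkg7 0.14).

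The remaining lists did not pass. Of the Immediate-early and dissociation stress genes 12 of 20 were higher (mean 0.26, adjusted p 0.737). The heat shock gene Hspa1b, from 4.60 ± 2.06 to 8.50 ± 1.59 (SD, n = 4 each), and Ier3 (-0.86) passed over the list alone. Of the Unfolded protein response genes 11 of 21 were higher (mean 0.12, adjusted p 0.219), and asparagine synthetase, Asns, passed over the list alone (0.94 ± 0.21, SE), with the kinase Eif2ak3 at 0.69. The p53 target genes had 9 of 16 higher (mean 0.01, adjusted p 0.782), and 3 passed over the list alone, Sesn1 (-0.65), Phlda3 (0.69) and Cdkn1a. The RNA-binding proteins related to Musashi or active in stem cells had 7 of 15 higher (mean -0.05, adjusted p 0.896), with Dazap1 at 0.32. The deleted gene Msi2 is itself among the 15, at -1.12, and enters this mean. Of the genes chosen in advance without regard to a list, Numb, a known target of Musashi proteins, differed by -0.05, Kit by 0.34 ± 0.18 (SE), Myc by 0.16 and Ikzf2 by -0.32. Cdkn1c and Il7r were listed at 0, and Ly6a was not analysed here.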

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

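In this part, the tests of the erythroid and stem cell pattern, of the Msi2 signal, and the splits for genes and probe sets past the adjusted threshold were chosen only after the result was seen. A single array lay far from the other 3 of its group for 17 of 238 groups of 4 values, where chance gives about 1 in 20, or 11.9. 8 of the 17 fell on Msi2 KO 3, 3 on Msi2 KO 4, 2 on control 1, 1 on control 2, 2 on control 3, 1 on control 4, and 0 on Msi2 KO 1 or Msi2 KO 2.

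On Msi2 KO 3, Blvrb was high at 9.80 (others 8.58 to 8.78), while 4 genes were low. These were Cd74 at 5.83 (others 8.40 to 8.87), Pecam1 at 6.58 (7.29 to 7.43), Cd34 at 9.68 (10.42 to 10.55) and Hlf at 7.07 (9.85 to 10.22). Its list means were low for the HSC-enriched genes at -1.46 (others -0.26 to -0.21), the dendritic cell and MHC class II genes at -1.16 (0.43 to 0.73) and the cell cycle inhibitors at -0.42 (-0.10 to -0.04). Msi2 KO 4 was high for Fcer1a at 7.83 (others 6.46 to 6.62), Nkg7 at 10.34 (9.60 to 9.65) and Pf4 at 11.64 (10.36 to 10.55). Control 1 was low for Mpo at 12.58 (others 12.92 to 12.98) and for the myeloid-primed list at -0.70 (0.19 to 0.28). Control 2 was high for Cyp51 at 8.51 (others 8.12 to 8.17). Control 3 was high for Ccdc71l at 7.37 (others 6.85 to 6.88) and low for the multipotent and lymphoid-primed list at -0.12 (0.03 to 0.05). Control 4 was low for Znrd2 at 6.90 (others 7.31 to 7.37).

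Erythroid genes were higher and genes of stem cells and lymphoid-primed progenitors lower in Msi2 KO, and whether Msi2 KO 3 alone carries this stays open: without it camera gave an adjusted p of 1.2e-06 for the erythroid list (mean 0.66), 0.0498 for the lymphoid-primed list (-0.23) and 0.0674 for the HSC-enriched list (-0.23), adjusted p = 0.579, 0.596 and 0.579 with an estimated correlation, and two-sided exact permutation p 0.114, 0.0857 and 0.0571, with 2, 2 and 3 of the other 3 KO arrays outside the controls. With Xist as a covariate the differences did not shrink, at 1.20 for the erythroid, -0.63 for the HSC-enriched and -0.61 for the lymphoid-primed list. Camera's largest adjusted p there was 4.92e-05 at the preset correlation, and no estimated correlation was run in that setting. Labels exchanged only within the high-Xist and low-Xist arrays gave an exact permutation p of 0.0333 for each list, the smallest that 30 assignments can give. Since the 3 lists were chosen after the result was seen, these tests cannot exclude the uneven numbers of high-Xist and low-Xist arrays as a cause. The low-Xist arrays alone hold 1 control and test little. Their differences were -0.24 for the HSC-enriched and -0.14 for the lymphoid-primed list, against -0.84 and -0.86 in the high-Xist arrays. A lower purity that raises every other blood cell alike stays open, since the erythroid list exceeded the 7 other mature blood cell lists by 0.796 (SD 0.181 in controls and 0.976 in KO, two-sided exact permutation p 0.0571; 1.11 and exact p 0.0286 against the B, T and NK, and neutrophil lists alone), of which the mast cell list (0.87) and the macrophage list (0.59) were higher and the B cell list (-0.52) lower. More myelo-erythroid progenitors within the LSK gate may also give such a pattern. The myeloid-primed list leaves this open at a mean of 0.071 (camera adjusted p 0.896, and adjusted p = 0.964 with an estimated correlation). With Xist as a covariate it passed camera at 0.27 (adjusted p 0.0102), at the preset correlation only, while its correlation estimated without the covariate was 0.467. The only low-Xist control, control 1, had a myeloid-primed mean of -0.70, against 0.19 to 0.28 on the other controls. The difference was 0.50 in the low-Xist arrays and 0.11 in the high-Xist arrays, so this rise leans on that control. No other list holds any of the 19 erythroid genes, 9 of them lie above the median level of all genes in the controls, the abundant globin gene Hba-a2 stayed at 11.55 in controls and 11.43 in KO, and an effect of the Msi2 genotype within the same cells was not tested and stays open.

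Msi2 signal differed widely among the KO arrays, from 15.1% to 72.6% of the control mean. The log2 SD was 1.02 over the KO arrays and 0.12 over the controls, which does not decide whether the probe sets lie outside the deleted part, since loss of the transcript can lower those as well. On Msi2 KO 3, the 1996 probe sets within 1 log2 of Msi2 in the controls had a median difference of 0.023 (SD 0.535). Of these, 8 (0.401%) fell by at least as much as Msi2, at -2.72, so few probe sets of like level fell as far. Whether the whole array was dimmer before normalization stays open, since quantile normalization brings all arrays to like levels. Cells that keep an intact allele, a changed mix of cells and a difference between mice could each give an uneven signal, and these were not tested and stay open.

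The counts of the comparison were set against all 35 splits of the 8 arrays into 4 and 4. For genes at an unadjusted p under 0.05, 1 split, the real one, gave a count as large (1222, highest other 918). The same holds for genes whose groups do not overlap, with 1 split (762, highest other 591), a related count from the same values. First place is the best rank that 35 splits allow, and several counts were ranked. These ranks therefore argue against chance without excluding it. For lists, 11 splits gave as many as the real 10 (highest other 15), so chance is not excluded. For genes and for probe sets past limma's adjusted threshold, where the real counts are 0, all 35 splits gave as many (highest other 1 each), with 1222 genes and 2371 probe sets at an unadjusted p under 0.05. The split with 918 genes, and that with 591, put all 3 arrays with low Xist on the same side.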

How the results depend on the processing

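The analyses by Xist, the exact permutation of list means and the analyses that keep probe sets listed at 0 were chosen only after the data were seen. No gene passed in limma except under 2 alternatives, with 1222 at an unadjusted p under 0.05 as reported. These gave 1 gene without Msi2 KO 1 (Zg16) and 5 genes with Xist as a covariate (Fcer1a, Fscn1, Mt1, Nhsl1 and Psma8), whose cause was not tested. Without each array in turn the counts were 0 to 1 genes, 0 to 1 probe sets and 6 to 12 lists (6 without Msi2 KO 3), and Msi2 lay between -1.43 and -0.55. Probe sets passed as follows, against 0 as reported: 1 with repeated quantile normalization and 1 without shared probe sets (Aplp2), 1 without genes below the median level (Elovl1), 2 with an intensity trend and robust prior (both), and 3 with array weights (both and Psma8). In the gene fit as reported brighter probe sets stand for Aplp2 and Elovl1, and neither gene passed the gene fit in these settings. Fewer tests enter without shared probe sets or genes below the median level, and otherwise the cause was not tested. With the replicate number as a block the counts were 0 genes, 0 probe sets and 11 lists, and Msi2 was -1.12. The deviations of same-numbered arrays correlated at 0.137, -0.172, 0.0751 and -0.0207, which shows no clear pairing. With so few arrays this cannot exclude one, and the labels do not say what the numbers mean.

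The 10 lists all passed under repeated quantile normalization, median centring, the mean of all probe sets, leaving out shared probe sets, an intensity trend, the replicate block and Xist as a covariate. They became 0 with an estimated correlation, 0 by fry and 0 by exact permutation, which after adjustment could hardly pass with so few arrays. The correlations estimated for the 10 ran from 0.0382 to 0.545, against camera's preset of 0.01. Array weights left out the MLL and Hox list and the S phase list, ranks the mast cell list, and the median filter the HSC-enriched list. That filter left too few members of the B cell and mast cell lists to test, and it added the cell cycle inhibitor and cholesterol synthesis lists. Array weights added the macrophage list, the mean of all probe sets the TGF-beta pathway list, and the replicate block the stromal and endothelial list. The intensity trend and ranks each added the cytosolic ribosomal list. Xist as a covariate added the myeloid-primed, stromal and endothelial, TGF-beta pathway and Notch lists. The arrays with low Xist (1 control, taken to vary like the KO arrays) gave 7 lists, 2 of them among the 10 (erythroid and mast cell; the HSC-enriched and lymphoid-primed lists were lost), and those with high Xist 15.

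These values turned direction, and the cause was not tested. With median centring the p53 target genes were at -0.0053. Without genes below the median level, p53 target genes were at -0.10 and immediate-early genes at -0.072. With the mean of all probe sets Numb was at 0.0090, and without shared probe sets Slc2a3 at 0.33. With array weights Slamf1 was at 0.12, Tgfbr2 at -0.010, myeloid-primed genes at -0.0071 and p53 target genes at -0.047. With Xist as a covariate Numb was at 0.024, Tgfbr2 at -0.083, Mpo at 0.062 and cholesterol synthesis genes at 0.00040. In arrays with high Xist, dendritic cell genes were at -0.39, p53 target genes at -0.12 and immediate-early genes at -0.21. The immediate-early list passed camera in that direction at the preset correlation (adjusted p 0.0152). Over all 8 arrays it had an adjusted p of 0.914 by camera with an estimated correlation. Arrays with low Xist gave 0.81 for that list, against 1 control. In those with low Xist, T and NK cell genes were at 0.086, TGF-beta target genes at 0.014, MYC target genes at -0.029, G2 and M phase genes at -0.018, cell cycle inhibitors at 0.11 and cholesterol synthesis genes at 0.14.

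Leaving out each array turned the direction in these ranges: Myeloid-primed progenitor genes -0.16 to 0.18, Megakaryocyte and platelet genes -0.094 to 0.21, p53 target genes -0.035 to 0.046, Numb -0.18 to 0.038, Mpo -0.12 to 0.026, Cholesterol synthesis genes -0.10 to 0.055, Slamf1 -0.45 to 0.25, Tgfbr2 -0.12 to 0.22, Dendritic cell and MHC class II genes -0.044 to 0.59, Meis1 -0.38 to 0.084, TGF-beta target genes -0.17 to 0.028, Nkg7 -0.038 to 0.21, and G2 and M phase genes -0.056 to 0.080. Of the other single genes and lists, leaving aside the runs without 1 array, 1113 values kept direction and side of the threshold, 41 lost and 23 gained a call. Since no gene passed as reported, most of the values that kept their side missed the threshold in both settings. The other set tests used the reported list means, so their direction could not turn. The median of all genes moved by at most 0.02. How signal over background limits the results is not known, since the 7474 genes listed at 0 include the ribosomal genes Rps16 and Rps27, so a 0 is not read as low signal.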

Other observations

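In this part, the genes described first, the relations between Msi2 and the list means, and the choice of the further lists came only after results were seen, while the tests of the further lists were set before their own results were seen. The genes named next were picked for their values and form no tested group. The metallothioneins Mt1 and Mt2, which bind zinc and copper, read 8.22 and 7.05 in controls and 9.68 and 9.07 in KO, differences of 1.46 ± 0.42 and 2.01 ± 0.70 (SE, n = 4 against 4). The heat shock genes Hspa1a (2.02 ± 0.83) and Hsph1 (0.77 ± 0.26) were higher too. On 3 KO arrays, all but Msi2 KO 3, C1qb (2.36 ± 1.23), Cd5l (1.05 ± 0.51) and Hmox1, heme oxygenase (1.35 ± 0.71), lay above every control. They are members of the macrophage and monocyte list, which had 9 of 13 members higher and 4 lower and missed the camera threshold (adjusted p 0.0817). The iron exporter Slc40a1 (1.32 ± 0.57) lay above every control on 3 KO arrays as well. None of these genes passed limma's adjusted threshold by group alone; Mt1 did with Xist as a covariate.

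The surface protein Cd244a went from 9.50 ± 0.20 to 8.25 ± 0.58 (SD, n = 4 each), below all controls on 4 of 4 KO arrays, and Thy1 from 7.80 ± 0.46 to 6.05 ± 0.87, below them on 3. Il6st, the shared receptor chain of the IL-6 family, was lower by 1.57-fold, and the secreted protein Fstl1 by 2.96-fold. The imprinted transcripts Meg3 (6.50 to 5.14) and Rian (6.89 to 4.72) of the Dlk1 region were lower, although the controls themselves spread from 5.37 to 8.35 for Rian. Mitochondrial genes Bcs1l (0.77 ± 0.16, SE), Pitrm1 (0.71 ± 0.15) and Mrpl12 (0.76 ± 0.19) were higher on 4 of 4 KO arrays. None of these passed limma's adjusted threshold either.

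A first hypothesis was that arrays with less Msi2 signal have more erythroid signal within the groups. Over 8 arrays, as deviations from their group means, Pearson's r was -0.895 (permutation p 0.00694, adjusted 0.0139) and Spearman's rho -0.881 (permutation p 0.0174, adjusted 0.0347), from 576 rearrangements within the groups and 2 relations tested. Without Msi2 KO 3 and Msi2 KO 1 r was -0.586, so the direction remained and the size rests in part on those arrays. Xist level goes with both measures within the groups, and the rearrangements did not hold it fixed. The low-Xist arrays Msi2 KO 1 and Msi2 KO 2 had more Msi2 signal (72.6% and 63.4%) and lower erythroid means (0.34 and 0.66). The high-Xist arrays Msi2 KO 3 and Msi2 KO 4 had less Msi2 (15.1% and 40.5%) and higher erythroid means (1.97 and 0.97). The mix of cells may also drive both measures. The control with the most Msi2 signal (111%), which has low Xist, had the lowest erythroid mean (-0.43), and that with the least (91.1%) the highest (0.44). This relation therefore does not show an effect of Msi2 dose. For the HSC-enriched list r was 0.919 (permutation p 0.0556, adjusted 0.0556) and rho 0.762 (permutation p 0.0642, adjusted 0.0642), with r 0.519 without the same arrays, which missed the threshold and stays open.

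A further hypothesis, from the mitochondrial genes among those with the smallest p, was that mitochondrial ribosomal protein genes are higher too. Of 76 such genes 65 were higher, by 0.19 on average, and the mean was 0.10 without Msi2 KO 3. Camera gave p 1.19e-06 with its preset correlation and p 0.227 with the estimated correlation of 0.291, and the exact permutation p of the list mean was 0.171, so the hypothesis stays open. The last was that other imprinted genes are lower along with Meg3 and Rian. The data argue against it, since 9 of 14 were higher, by 0.14 on average, on 4 of 4 KO arrays (two-sided exact permutation p 0.0286), while camera gave p 0.348.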
